A study of Mus musculus with 4 samples.

How the data were processed

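Spleen mononuclear cells, sorted by flow cytometry, of mice of a hypoxia model (HAPC) and of control mice were profiled in 4 libraries, 2 per group, with the 10x Genomics 3' version 3 chemistry, per the labels' protocols. The authors deposited raw UMI counts per gene and barcode, and the submitters' processing notes name Cell Ranger 3.1.0 and the mm10 build. The labels give hypoxia exposure as the treatment protocol of all 4 samples, Control ones included, and the groups follow the labels' treatment characteristic. Replicate numbers follow the labels, and 0 deposited files were left unread. Of the gene IDs in the files, 99.61% matched the mouse GENCODE annotation used for positions.

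Cells with 500 or more UMIs, 200 or more genes and under 10% of UMIs from mitochondrial genes were kept. Doublets were called per library with scrublet in scanpy 1.11.5 (expected rate 0.08). It marked 1.07%, 1.28% and 0.711% of cells in Control replicate 1 and HAPC replicates 1 and 2. In Control replicate 2 it marked 0.0286%, under the 0.5% set as its minimum, so the 474 cells (6.79%) with the highest scores, a share proportional to the barcodes, were removed there. Counts were scaled to 10000 per cell, logged and reduced to 2000 variable genes and 30 principal components. Cells were joined to 15 neighbours and clustered with the Leiden method (igraph 0.11.9) at resolution 1, without integration of libraries. Erythroid-like cells were clustered again at resolution 0.6. Immunoglobulin and T cell receptor variable genes, mitochondrial, ribosomal protein and sex-linked check genes were left out of clustering.

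Clusters were named "-like" from markers fixed before the data were examined, with at least 3 markers detected. Unnamed clusters held 4.83% ± 0.391 of Control and 4.55% ± 1.93 of HAPC cells (SD, n = 2 each). Among them was cluster 15, whose leading genes were globins beside B cell markers, with 3.72%, 3.67%, 4.79% and 1.34% of cells per library. A macrophage-gene sub-cluster of erythroid-like cells was left without a stage after the data were seen. Car1 and Bpgm were naming markers of erythroid-like cells that also differed between groups (2 of 27 tested), and Car1 was the only one of 37 stage markers to differ in intermediate cells.

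Shares of cells have exact 95% Clopper-Pearson intervals, which cover counting error only, and exact two-sided permutation tests, whose smallest p is 0.333 with 2 libraries against 2. Cell numbers per class and stage were tested with edgeR 4.0.16's quasi-likelihood test with the log of the library's cells as offset and a spread without an abundance trend. UMIs were summed per library and class, classes with under 20 cells in a library were not tested, and genes were tested with edgeR (TMM, filterByExpr). P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 throughout. Standard errors are the absolute log2 fold change over the square root of F. Differences in response between classes were not tested. Gene lists fixed before the data were examined were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with an estimated correlation and fry as alternatives. DESeq2 1.42.0 was another test. Positions are 1-based.

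Named genes were chosen by a rule fixed before the data were examined. In erythroid-like cells it took up to 10 higher and 10 lower genes with the largest log2 fold change among those passing, with a mean log2 CPM of at least 5 and no overlap between groups, leaving out unnamed gene models and receptor segments. A fixed panel of 17 genes and the 3 members with the smallest p of each called list were added. Other classes and stages took up to 5 genes each way and 2 members per called list. Some genes chosen by the rule are not reported here.

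The tests were first tested on simulated counts with 200 changed genes. For erythroid-like cells (9850 genes) edgeR recovered 23.2% of genes changed by 1 and 76.8% of those changed by 2 on the log2 scale, with 5 false calls. For B cell-like cells (11487 genes) it recovered 75.5% and 98.0%, with 19 false calls. With no gene changed there were 0 and 3 false calls, and in erythroid-like cells 1 list was called.

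Alternatives set before the data were examined covered scaling, DESeq2, the expression filter, globin removal, thinning to the smallest library, doublets, UMI and mitochondrial limits, cluster resolution, genes over 10 times higher in another class, the replicate number as a block, and leaving out each library. Added after the data were seen were 50 or more genes per cell, every barcode with 200 or more genes for the gene tests, an equal doublet share in every library, removal of erythroid-like cells that carry 3 or more of 8 B cell or 8 T cell genes, alone and with the macrophage-gene sub-cluster, addition of the mixed cluster, a crossed pairing, an abundance trend, shares of the named stages alone and tests of single clusters. Analyses ran in Python 3.11.15 and R 4.3.3.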

Results

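Spleen mononuclear cells sorted by flow cytometry from mice of a hypoxia model, named HAPC in the labels, were compared with those of controls, which the series describes as healthy, by droplet single-cell RNA sequencing. Each group held 2 libraries, and the library was the replicate. The deposited tables held 10597 and 8480 barcodes in Control replicates 1 and 2 and 9782 and 9208 barcodes in HAPC replicates 1 and 2. Total UMI counts, which count single captured transcripts, were 82235215, 59587787, 73437863 and 86875408 in the same order. After filtering, 8840, 6508, 7186 and 7961 cells were kept, with a median of 5921, 5231.5, 5196.5 and 6465 UMIs per cell. Transcripts of the 4 adult globin genes made up 11.9% and 14.95% of all UMIs in the Control libraries and 29.3% and 27.6% in the HAPC libraries. Reads of the Y-linked gene Ddx3y were present in all 4 libraries (15023, 9111, 6974 and 8860 UMIs).

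The first comparison asked how the make-up of the sorted spleen mononuclear cells differed between the groups. Erythroid-like cells, named from globin, heme and red cell membrane genes, made up 21.9% ± 5.77 (SD, n = 2) of HAPC cells and 5.01% ± 1.42 (SD, n = 2) of Control cells, a 4.38-fold higher share. Their share was 4.005% and 6.01% in the Control libraries and 17.9% and 26.0% in the HAPC libraries. The model of cell numbers called them higher (log2 fold change 2.13, SE 0.52, adjusted p = 0.00507 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11 classes). B cell-like cells made up 51.1% ± 3.20 of Control and 34.8% ± 5.18 of HAPC cells (SD, n = 2 each). This difference did not pass the test (log2 fold change -0.55, edgeR adjusted p = 0.509).

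Neutrophil-like cells made up 0.904% ± 0.0177 of Control and 2.32% ± 0.934 of HAPC cells (log2 fold change 1.36, edgeR adjusted p = 0.0910). This class joined cluster 11, led by Thbs1, Retnlg and Csf3r, and cluster 28, led by the granule genes Camp, Ngp and Ltf. Cluster 28 held 0.181% and 0.0922% of Control cells and 0.668% and 2.05% of HAPC cells. At resolution 2 a monocyte-like cluster of 165 cells, led by Thbs1, Ace and Fn1, stood apart. Neutrophil-like cells then made up 0.428% ± 0.0460 of Control and 1.73% ± 0.949 of HAPC cells (log2 fold change 2.01, edgeR adjusted p = 0.0277). Dendritic cell-like cells made up 10.1% ± 3.97 and 5.86% ± 2.55, and NK cell-like cells 3.81% ± 1.73 and 1.96% ± 0.689, of Control and HAPC cells (edgeR adjusted p = 0.365 and 0.270). T cell-like cells made up 16.7% ± 1.296 and 20.1% ± 1.95, macrophage-like cells 4.88% ± 1.32 and 5.37% ± 1.89, progenitor-like cells 1.003% ± 0.614 and 1.66% ± 0.935, and plasma cell-like cells 1.09% ± 0.540 and 0.890% ± 0.139, and none of these passed the test. Shares of a whole are tied to one another, and an exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.333. This is the value for erythroid-like and B cell-like shares. The erythroid call was lost without Control replicate 1 (log2 fold change 1.87, edgeR adjusted p = 0.189) and without HAPC replicate 2 (1.84, adjusted p = 0.107).

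**Figure D1:**
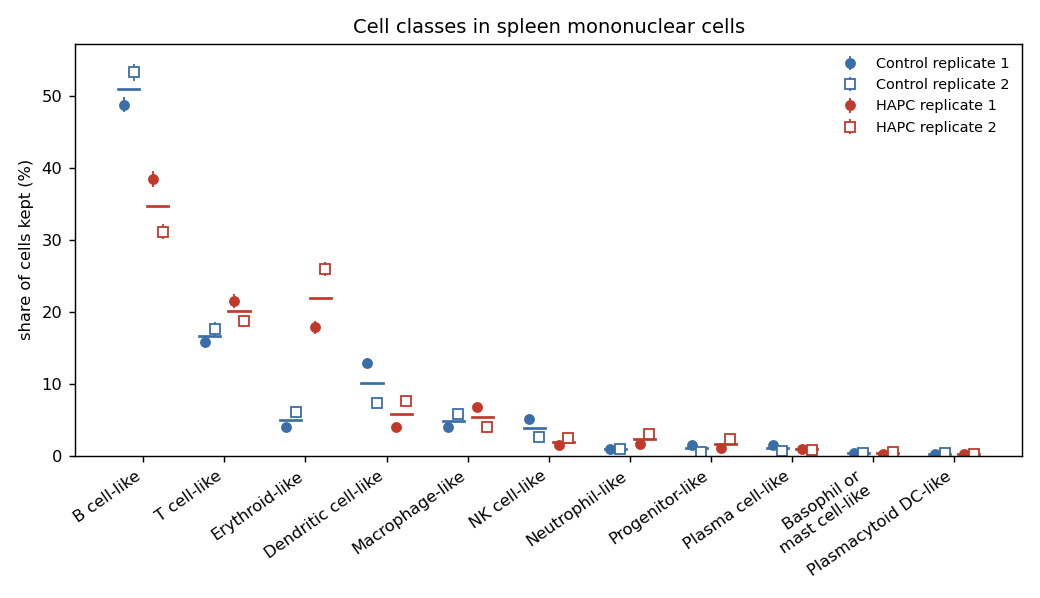
Share of the cells kept (%) in each named class, per library, with exact 95% Clopper-Pearson intervals that cover counting error only; short lines are group means. Erythroid-like cells lie at 4.005% and 6.01% in the Control libraries and at 17.9% and 26.0% in the HAPC libraries.

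Within the erythroid-like cells, early cells were more frequent and late cells less frequent in HAPC libraries. Early erythroid-like cells, named from genes of the first committed precursors, made up 5.37% and 7.93% of erythroid-like cells in the Control libraries and 16.7% and 15.6% in the HAPC libraries (log2 fold change 1.26, SE 0.18, edgeR adjusted p = 0.00711). Late erythroid-like cells made up 43.2% and 42.7% against 33.4% and 34.4% (log2 fold change -0.34, SE 0.05, edgeR adjusted p = 0.00711). Intermediate erythroid-like cells made up 12.99% and 16.4% against 20.03% and 25.3% (log2 fold change 0.63, SE 0.21, edgeR adjusted p = 0.0546). Sub-clusters left without a stage name held 38.4%, 33.0%, 29.9% and 24.7% in the same order. When the 10 sub-clusters were tested instead of the 3 stages, 0 passed by edgeR (4 at an unadjusted p under 0.05; smallest adjusted p = 0.0677). Both stage calls were lost without Control replicate 1 (edgeR adjusted p = 0.114 for early and 0.178 for late cells) and without Control replicate 2 (0.0512 and 0.167).

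**Figure D2:**
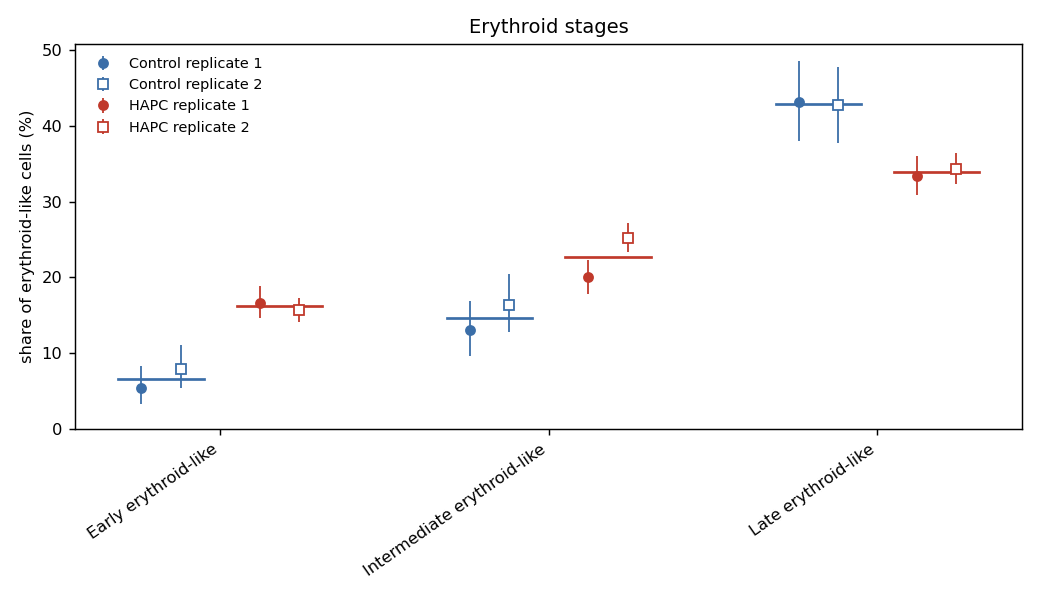
Share of erythroid-like cells (%) in each named stage, per library, with exact 95% Clopper-Pearson intervals that cover counting error only; short lines are group means. Early cells lie at 5.37% and 7.93% in the Control libraries and at 16.7% and 15.6% in the HAPC libraries.

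The study's title names the molecular features of spleen erythroid cells as its subject, so gene expression was compared in the UMIs summed over erythroid-like cells of each library. Pclaf, a partner of the replication clamp, Hist1h1a, a linker histone, Cenph, a kinetochore protein, and Dut and Dtymk, enzymes of thymidine nucleotide supply, rose in HAPC erythroid-like cells. Car1, the carbonic anhydrase of early erythroid precursors, rose from 156 ± 3.99 to 348 ± 20.8 CPM (SD, n = 2 each; log2 fold change 1.16, SE 0.17). Cd79b, part of the B cell receptor, fell from 68.8 ± 20.6 CPM in Control to 10.7 ± 3.80 CPM in HAPC (log2 fold change -2.69, SE 0.32). Plac8 fell from 152 ± 81.5 to 22.4 ± 5.17 CPM (log2 fold change -2.77, SE 0.38). Each of these 8 genes had an adjusted p of 0.0445 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, except Dut (0.0486). Without the erythroid-like cells that carried lymphocyte markers, Pclaf, Hist1h1a, Cenph, Dut, Dtymk and Car1 did not pass (log2 fold changes 0.64, 0.49, 0.45, 0.34, 0.38 and 0.50). Cd79b and Plac8 passed (-3.15 and -2.09), but Cd79b was among the 8 B cell genes that marked cells for removal, so its value there depends on that removal.

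In all, 414 of 10016 genes passed, 50 higher and 364 lower in HAPC. DESeq2 called 936, and other cell filters, cluster resolutions and doublet removals gave 0 to 3791 by edgeR. The 10 higher genes named by the fixed rule were Car1, Pclaf (log2 fold change 1.16), Cenph (1.15), Bex4 (1.13), Ccdc34 (1.06), Hist1h1a (0.98), Dtymk (0.97), Gstm5 (0.96), Siva1 (0.95) and Dut (0.94). The 10 lower genes were Plac8, Cd79b, Ms4a1 (-2.55), Cd79a (-2.22), Cd37 (-2.15), Klf2 (-2.15), Tsc22d3 (-2.14), Cytip (-2.12), H2-DMa (-2.12) and Klf6 (-2.12). Of the 364 lower genes, 326 had a mean CPM over 10 times higher in another cell class, as did 1 of the 50 higher genes (Ier3) and 2979 of all genes tested. Erythroid-like cells carrying 3 or more B or T cell genes made up 22.1% ± 1.55 of the class in Control and 11.1% ± 5.41 in HAPC libraries (SD, n = 2 each). Without those cells 183 genes passed, 3 higher and 180 lower, of which 53, 2 higher and 51 lower, were called the same way among the 414. With the genes over 10 times higher in another class left out, 0 of 7037 passed by edgeR, with 1507 at an unadjusted p under 0.05. Scaling by library size alone called 1346 higher and 355 lower genes and moved the median of all genes to 0.28 on the log2 scale. The count was 120 (8 higher) without Control replicate 1, 1750 (510 higher) without Control replicate 2 and 1070 (112 higher) without HAPC replicate 1.

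Car1 (ENSMUSG00000027556) lies on chromosome 3 from 14766216 to 14808368, Pclaf (ENSMUSG00000040204) on chromosome 9 from 65890237 to 65903266, Cd79b (ENSMUSG00000040592) on chromosome 11 from 106311341 to 106314762 and Plac8 (ENSMUSG00000029322) on chromosome 5 from 100553725 to 100572245, all protein-coding genes of the mm10 build.

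The reported genes of a panel of red cell and hypoxia genes, set before the data were examined, did not pass the test. The adult globins Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had log2 fold changes of -0.40, -0.55, -0.52 and -0.49 (edgeR adjusted p = 0.233 to 0.399). The red cell regulators Gata1 and Klf1 had 0.67 and 0.74 (edgeR adjusted p = 0.150 and 0.0894). The erythropoietin receptor gene Epor had 0.43, the transferrin receptor gene Tfrc 0.30, the heme synthesis gene Alas2 -0.38 and the stem cell factor receptor gene Kit -0.81. Genes induced by low oxygen gave -0.47 for Bnip3l, -2.06 for Vegfa and -1.34 for Slc2a1, and Vegfa and Slc2a1 stood at 2.87 and 4.19 CPM in Control. Hmox1 had -0.25, and the alarmins S100a8 and S100a9 had 2.46 and 2.52 at 6.38 ± 6.92 and 8.92 ± 8.73 CPM in HAPC (SD, n = 2).

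Among 25 gene lists tested in erythroid-like cells, 9 were called by camera with a preset correlation. S phase genes were higher as a group: all 26 members had a positive log2 fold change (median 0.77), 5 passed over all genes and 25 adjusted over the list alone, with Mcm6 at 0.86 and Rrm1 at 0.88 (camera adjusted p = 1.62e-10). The 26 G2 and M phase genes (median 0.47) and the 40 nuclear genes of oxidative phosphorylation (median 0.44) were all positive, with 0 members passing by edgeR either way (camera adjusted p = 1.50e-05 and 1.63e-08). MHC class II antigen presentation genes were lower, with 10 of 14 passing over all genes and 14 adjusted over the list alone, among them Cd74 at -2.09 and Cd86 at -1.95. Interferon response genes were lower, with 5 of 25 passing and 16 adjusted over the list alone, among them Ifi27l2a at -2.47, Ifit1 at -1.69 and Oasl2 at -1.81. MHC class I genes (2 of 18 lower, 13 adjusted over the list alone) and immediate early genes (5 of 20 lower and 1 higher, 14 and 1 adjusted over the list alone) were lower as groups. Psmb8 stood at -1.65 and Egr1 at -1.47, and Ier3 rose by 1.25. The 13 mitochondrially encoded genes (median -0.71) and the 22 autophagy genes (median -0.41) were lower as groups, with 0 members passing over all genes and 1 and 0 adjusted over the list alone. With an estimated correlation none of the 9 was called, and each had an adjusted p = 0.756 (fry adjusted p = 0.267 to 0.298). Without the lymphocyte-marked cells, S phase genes had a median of 0.29 with 0 passing over all genes or adjusted over the list alone. Their camera adjusted p was 3.54e-05, and 0.515 with an estimated correlation. The G2 and M phase call was lost (median 0.03, camera adjusted p = 0.552). The 40 nuclear oxidative phosphorylation genes had a median of 0.11, with 0 passing over all genes or adjusted over the list alone. Their camera adjusted p was 0.0205, and 0.515 with an estimated correlation. MHC class II and interferon response genes then had medians of -2.25 and -1.17, with 4 of 12 and 7 of 22 lower over all genes. Adjusted over the list alone, 10 and 19 were lower (camera adjusted p = 4.56e-08 and 1.63e-12, and 0.537 and 0.515 with an estimated correlation). In the cells left, the median was 0 Cd74 UMIs per cell in each library, and the 5% of cells with the most held 58.1% to 71.7% of it. Their MHC class II UMIs stood at 479 and 167 CPM in the Control and 88.0 and 115 CPM in the HAPC libraries, so the fall was largest against Control replicate 1. Sub-cluster 8, led by the macrophage genes C1qa, C1qb and C1qc, made up 8.76% and 8.18% of erythroid-like cells in the Control and 5.61% and 2.51% in the HAPC libraries. Without it and the lymphocyte-marked cells, MHC class II genes had a median of -1.77, with 0 of 10 passing over all genes and 7 lower adjusted over the list alone (camera adjusted p = 9.25e-05; adjusted p = 0.583 with an estimated correlation). The oxidative phosphorylation call was lost there (median 0.0880, camera adjusted p = 0.0571). Without the lymphocyte-marked cells alone, 3 of 13 mitochondrially encoded and 7 of 22 autophagy genes were lower over all genes and 12 of each adjusted over the list alone (medians -0.85 and -0.62, camera adjusted p = 3.85e-06 and 1.07e-05; adjusted p = 0.633 and 0.537 with an estimated correlation). With all erythroid-like cells, the mitochondrially encoded call was lost without HAPC replicate 2 (camera adjusted p = 0.0979), and the autophagy call without Control replicate 2 (0.357), HAPC replicate 1 (0.215) or HAPC replicate 2 (0.0744) and with scaling by library size alone (0.111).

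The lists on globins, heme synthesis, iron handling, the red cell membrane, erythroid transcription factors with erythropoietin signalling, hypoxia targets and glycolysis were not called (camera adjusted p = 0.144, 0.576, 0.235, 0.366, 0.962, 0.366 and 0.366). The hypoxia list had 1 of 16 tested members lower and the glycolysis list 3 of 18 lower, and neither had a higher member. Hilpda was lower by -2.13 and Pkm, Pgam1 and Bpgm by -2.03, -1.48 and -0.96. Of the globins tested, Hbq1a passed at -1.35. Members named here were chosen after their values were seen. The lists on antioxidant defence, apoptosis, p53 targets, immunoregulatory genes, neutrophil granules, inflammatory cytokines, heat shock, the unfolded protein response and ribosomal proteins were not called either (camera adjusted p = 0.0583 to 0.984). Without the lymphocyte-marked cells, 5 of 7 globin genes were lower over all genes and 6 adjusted over the list alone (median -1.07, camera adjusted p = 1.34e-05; adjusted p = 0.515 with an estimated correlation). Red cell membrane genes were then called lower (median -0.24, 1 of 20 lower over all genes and adjusted over the list alone) and ribosomal protein genes higher (median 0.22, 0 of 38 either way), with camera adjusted p = 0.00166 and 1.61e-05 and adjusted p = 0.633 each with an estimated correlation. The hypoxia and glycolysis lists then had medians of -0.13 and -0.0084, with 1 of 14 and 1 of 15 members lower over all genes. Adjusted over the list alone, 2 were lower in each and 1 was higher in the glycolysis list (camera adjusted p = 0.403 and 0.517).

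**Figure D3:**
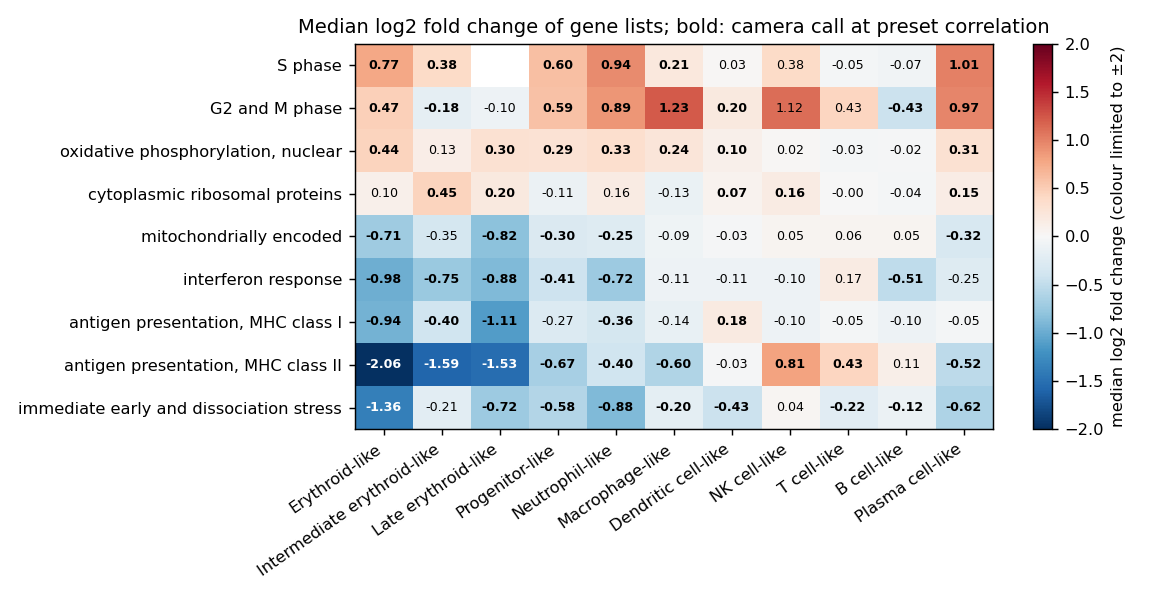
Median log2 fold change (HAPC against Control) of 9 gene lists in each class; bold values were called by camera at a preset correlation of 0.01, and colours are limited at 2 either way. S phase stands at 0.77 and MHC class II at -2.06 in erythroid-like cells, and no call held with an estimated correlation.

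Within intermediate erythroid-like cells, Asns and ribosomal protein genes rose and Cd74 and B2m of antigen presentation fell. Asns, which makes asparagine, rose from 5.01 ± 2.55 to 40.0 ± 13.5 CPM (SD, n = 2 each; log2 fold change 3.23, SE 0.49, edgeR adjusted p = 0.000854). The Control libraries held 46 and 64 intermediate cells with 441690 and 974099 UMIs, so the Control level of Asns rests on a few UMIs. The ribosomal protein genes Rpsa and Rplp0 rose by 0.96 and 0.78 on the log2 scale, and Car1, Tnfrsf13c and Ier3 by 1.38, 1.499 and 1.12. Tmsb4x, Cd74, B2m, Apol11b and Gda fell by 2.23, 2.03, 0.85, 0.82 and 0.77. Cd74 was detected in 47.8%, 29.7%, 28.0% and 26.0% of intermediate cells of Control replicates 1 and 2 and HAPC replicates 1 and 2. The share was 34.0%, 20.5%, 24.7% and 22.5% in T cell-like cells, which should lack it and had fewer UMIs per cell. In all 28 of 5247 genes passed, 17 higher and 11 lower. DESeq2 called 10 higher and 1 lower, with lymphocyte-marked cells left out 38 higher and 8 lower passed, and without genes over 10 times higher in another class 14 higher and 2 lower. Of the 38 ribosomal protein genes, 7 passed over all genes and 32 adjusted over the list alone (median 0.45, camera adjusted p = 3.41e-08; adjusted p = 0.787 with an estimated correlation, and camera adjusted p = 0.348 without Control replicate 2). Leaving out 1 library gave 126 genes (29 lower) without Control replicate 1, 77 (42 lower) without Control replicate 2, 18 (10 lower) without HAPC replicate 1 and 11 (3 lower) without HAPC replicate 2.

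Within late erythroid-like cells, genes of the interferon and antigen presentation lists fell. Irf7, a transcription factor of the interferon response, fell from 29.1 ± 7.87 to 12.2 ± 0.423 CPM (SD, n = 2 each; log2 fold change -1.23, SE 0.25, edgeR adjusted p = 0.00984), and Ifit1 fell by 1.42 and Ifi27 by 1.10. H2-D1, H2-K1, B2m, Cd74 and H2-Eb1 fell by 1.11, 1.42, 1.02, 1.51 and 1.56. Cd74 was detected in 29.4%, 19.2%, 18.6% and 17.3% of late cells of Control replicates 1 and 2 and HAPC replicates 1 and 2 (median 12623 to 13438 UMIs per cell), under its share of 34.0%, 20.5%, 24.7% and 22.5% in T cell-like cells, a class that should lack it (median 4949 to 5598 UMIs per cell). Apol11b fell by 1.04 and mt-Cytb, a gene of the mitochondrial genome, by 1.03, while Sept1 rose by 0.97. In all 26 of 2410 genes passed, 1 higher and 25 lower, and DESeq2 called 7. As groups, interferon response, MHC class II and immediate early genes were lower (2 of 12, 3 of 5 and 1 of 14 lower over all genes; 9, 5 and 6 adjusted over the list alone; camera adjusted p = 3.84e-07, 1.25e-06 and 1.29e-05), with adjusted p = 0.521, 0.589 and 0.521 with an estimated correlation. The count of genes was 4 (all lower) without Control replicate 1, 47 (44 lower) without Control replicate 2 and 16 (12 lower) without HAPC replicate 2. Early erythroid-like cells were not tested, since Control replicate 1 held 19 of them.

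**Figure D4:**
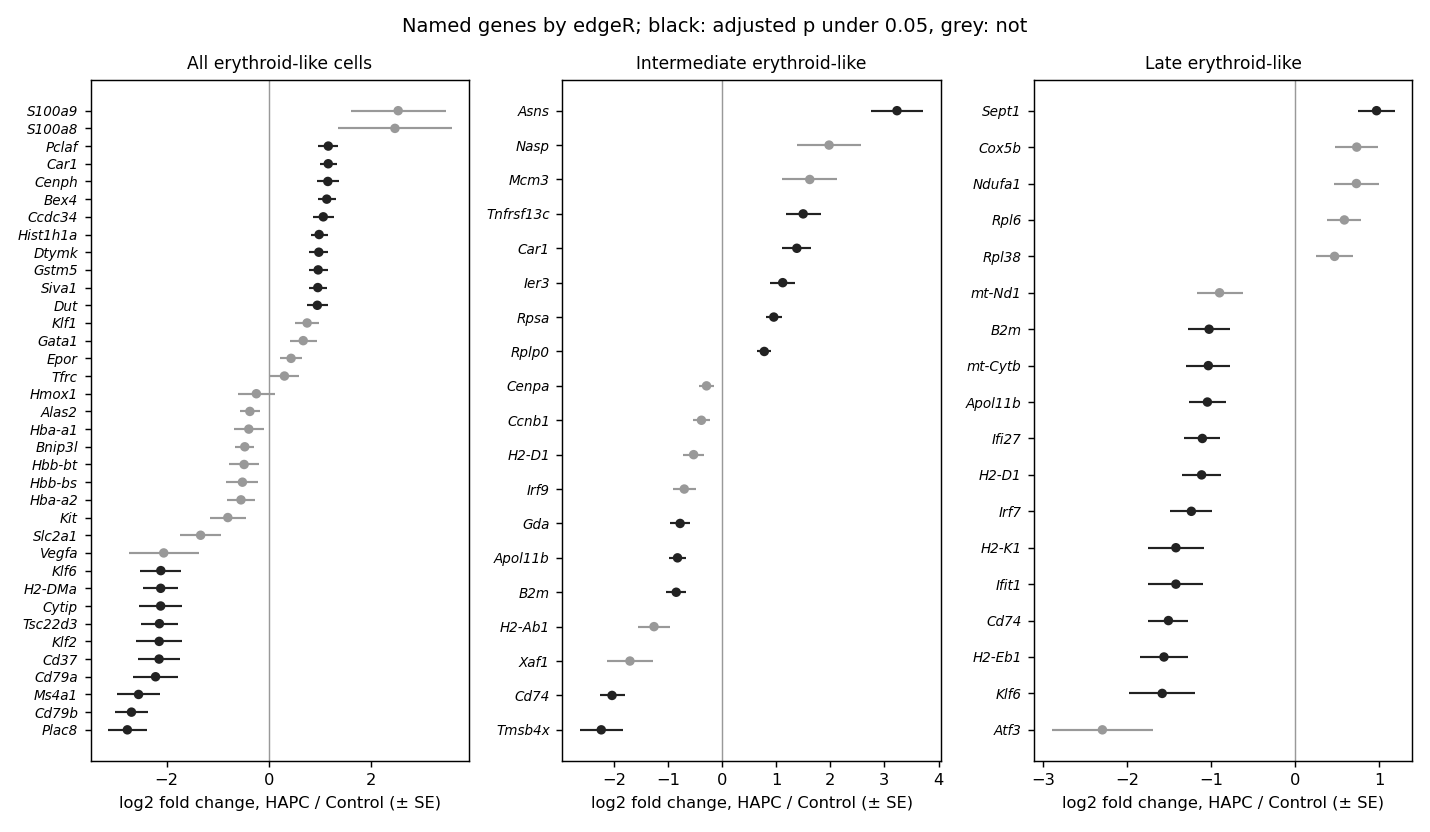
Log2 fold change (HAPC against Control, with SE) of named genes in all erythroid-like cells and in the intermediate and late stages; black points passed edgeR's test at an adjusted p of 0.05 and grey points did not. Car1 rose by 1.16 in all erythroid-like cells and by 1.38 in the intermediate stage.

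The other cell classes were compared in the same way. In dendritic cell-like cells 13 of 10712 genes passed, 6 higher and 7 lower. Lgals1, a galectin, rose from 103 ± 12.8 to 198 ± 13.3 CPM (SD, n = 2 each; log2 fold change 0.94). Cyp4f16, Ptgs2, the early response gene Egr1, the heme exporter gene Flvcr1 and Rhob fell by 1.14, 1.14, 1.11, 1.01 and 0.90. The make-up of this class differed, with cluster 10, whose leading genes include Ptgs2 and Cyp4f16, holding 749 of 1139 and 237 of 473 of its cells in the Control libraries and 101 of 291 and 240 of 610 in the HAPC libraries. In NK cell-like cells 11 of 7487 genes passed, all higher, led by the globins Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 (log2 fold changes 5.29, 5.46, 5.80 and 5.84) and Cd81 (1.67). Their globin UMIs averaged 3.15 ± 0.291 per cell in Control and 147 ± 85.5 in HAPC libraries (SD, n = 2 each). Their medians were 3 in both Control libraries and 7.5 and 11 in the HAPC libraries, near the 7 and 8 of HAPC B cell-like cells. Ahnak fell by 1.95 in neutrophil-like cells (clusters 11 and 28), Ly6d by 2.50 in progenitor-like cells, and Car1 rose by 4.91 in macrophage-like cells, the only gene passing in each. In plasma cell-like cells the segment Igkv16-104, named here after its values were seen, was the only gene to pass and was lower in HAPC. In B cell-like and T cell-like cells 0 genes passed by edgeR, with 1153 and 515 at an unadjusted p under 0.05, and DESeq2 called 65 and 11. Leaving out 1 library moved the dendritic cell-like count to 12 (11 higher and 1 lower) without Control replicate 1, 141 (82 lower) without Control replicate 2, 101 (57 lower) without HAPC replicate 1 and 33 (11 lower) without HAPC replicate 2. It moved the NK cell-like count to 6 (5 higher), 3 (0 higher), 84 (67 higher) and 24 (23 higher) without Control replicates 1 and 2 and HAPC replicates 1 and 2. Every higher call was lost without Control replicate 2.

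S phase genes were higher as a group in neutrophil-like, progenitor-like and plasma cell-like cells (medians 0.94, 0.60 and 1.01), with 0 members passing over all genes and 19 of 26, 11 of 26 and 1 of 21 adjusted over the list alone. Their camera adjusted p was 1.05e-13, 4.25e-10 and 1.79e-12, and adjusted p = 0.276, 0.568 and 0.593 with an estimated correlation. The make-up of neutrophil-like cells differed, with cluster 28 holding 16 of 81 and 6 of 58 of them in the Control libraries and 48 of 119 and 163 of 237 in the HAPC libraries. Neutrophil granule and alarmin genes were higher as a group in B cell-like, T cell-like and progenitor-like cells (medians 3.30, 3.20 and 2.74), with 0 members passing over all genes and 9 of 11, 6 of 7 and 7 of 8 adjusted over the list alone. Their camera adjusted p was 1.58e-06, 3.63e-08 and 4.45e-08, and adjusted p = 0.957, 0.912 and 0.568 with an estimated correlation. S100a8 and S100a9 together stood at 3.83 ± 1.27 CPM in Control and 40.0 ± 37.0 CPM in HAPC B cell-like cells (SD, n = 2 each), a class outside the neutrophil lineage. In HAPC libraries they averaged 35.5, 37.6, 26.3, 42.3 and 22.2 CPM in T, NK, dendritic, progenitor and plasma cell-like cells, against 114520 CPM in neutrophil-like cells. The levels in B and T cell-like cells are read as background. In HAPC replicate 1 progenitor-like cells stood at 45.8 CPM, against 13.8 and 13.2 CPM in B and T cell-like cells. In HAPC replicate 2 they stood at 38.9 against 66.2 and 57.7 CPM. In dendritic cell-like cells, which differed in make-up between the groups (749 of 1139 and 237 of 473 Control cells in cluster 10, 101 of 291 and 240 of 610 HAPC cells), immediate early genes were lower as a group (median -0.43, 1 of 21 lower over all genes, 13 adjusted over the list alone; camera adjusted p = 7.23e-07, adjusted p = 0.488 with an estimated correlation).

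Over all cells of each library, 2322 of 14890 genes passed, 1899 higher and 423 lower, a comparison that mixes cell make-up with expression. Car1 and Klf1 rose by 3.46 and 3.41 on the log2 scale. S100a8, S100a9 and Lcn2, genes of neutrophils, rose by 3.37, 3.27 and 3.49, and Rab30, Pik3r4, Cr2, Cd79b and Gzma fell by 1.33, 1.31, 1.24, 1.24 and 1.17 (edgeR adjusted p = 0.00743 to 0.0431). S100a8 stood at 418 and 280 CPM in the Control libraries and 1434 and 5805 CPM in the HAPC libraries. The count was 715 (52 lower) without Control replicate 1, 1164 (86 lower) without Control replicate 2 and 970 (62 lower) without HAPC replicate 2.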

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

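The equal doublet share, 50 or more genes per cell, every barcode with 200 or more genes for gene tests, removal of lymphocyte-marked cells, alone or with the macrophage-marked sub-cluster, addition of the mixed cluster, the crossed pairing, the abundance trend and shares of the named stages alone were tests chosen after the result was seen. A tested change counted as kept with the same direction and side of the threshold. A share difference counted as kept if it moved less than the replicates' spread. A count of calls was kept if it stayed within a fixed ratio of the reported count. Over all alternatives, 395 values of the comparisons were kept, 157 moved, 10 became called, 11 lost their call and 17 changed sign. The erythroid-like share stayed higher in HAPC in every alternative run, with a log2 fold change of 1.82 to 2.47. Unless stated, the cause of a change was not tested. Depth limits the rarer classes: Control replicate 1 held 354 erythroid-like cells and 19 early ones, and intermediate and late stages had 5247 and 2410 genes to test.

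The erythroid abundance call was lost with TMM over classes (log2 fold change 2.47, edgeR adjusted p = 0.0730), under 20% mitochondrial UMIs (2.09, adjusted p = 0.111) and with 50 or more genes per cell (1.82, adjusted p = 0.118), leaving 0 classes called in each. An abundance trend called 2 classes, with B cell-like cells at -0.55 (edgeR adjusted p = 0.0463). Neutrophil-like cells became a call, for 2 classes each, at resolution 2 (2.01), with 1000 or more UMIs (2.25), with every barcode with 200 or more genes (1.80) and with an equal doublet share (2.19). Monocyte-like cells formed a class of their own in these 4 settings, and also under 20% mitochondrial UMIs (neutrophil-like cells at 1.85, edgeR adjusted p = 0.168) and with 50 or more genes per cell (1.98, adjusted p = 0.172), where neutrophil-like cells were not called. As a share of cells that are not erythroid-like, which leaves the only called class out, 0 classes were called, and the difference was -9.35 percentage points for B cell-like and 8.13 for T cell-like cells. Uncalled values near 0 changed sign. Basophil or mast cell-like cells stood at 0.12 with TMM, 0.0867 as that share and 0.52 at resolution 0.5, where that class took in the progenitor cells (528 cells, against 107 and 421 in the 2 classes as reported). Plasmacytoid DC-like cells stood at 0.25, 0.21, 0.0171 with 1000 or more UMIs, 0.0183 under 20% mitochondrial UMIs, 0.0432 with every barcode and 0.00806 with an equal doublet share. Macrophage-like cells stood at -0.000437 with 1000 or more UMIs. Share differences moved to 0.607 points for that joint class at resolution 0.5, -0.355 for dendritic cell-like cells with every barcode, where a cluster of 1227 cells with leading genes of cluster 10 was named monocyte-like and a cluster of 1316 cells scoring as dendritic was left unnamed, and -1.04 for plasma cell-like cells at resolution 2.

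Leaving out 1 library gave 0 to 1 called classes, with log2 fold changes of 1.84 to 2.45 for erythroid-like, -0.93 to 0.24 for basophil or mast cell-like, -0.27 to 0.46 for macrophage-like, -0.72 to 0.33 for plasma cell-like, -0.50 to 0.45 for plasmacytoid DC-like and -0.0110 to 1.55 for progenitor-like cells. It gave 0 to 3 called stages and 0 to 8 sub-clusters, with 1.02 to 1.58 for early, 0.44 to 0.81 for intermediate and -0.36 to -0.32 for late cells. Intermediate cells became a call with the named stages alone (0.45), at resolution 0.3 (0.83) and at resolution 1.2 (0.86), where 2 sub-clusters were called.

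The number of genes called in erythroid-like cells ranged from 0 to 3791. It was 936 with DESeq2 (157 higher), 675 with its size factors, 2102 without the expression filter, 761 without globin genes, 1701 with library size only, 3648 with doublets kept, 3791 under 20% mitochondrial UMIs, 3446 with 50 or more genes per cell, 2132 with the mixed cluster and 1413 with an equal doublet share. By edgeR it was 0 at resolution 2, with 1000 or more UMIs, with every barcode with 200 or more genes and without genes over 10 times higher in another class, with 1425, 3942, 2944 and 1507 at an unadjusted p under 0.05. Without lymphocyte-marked cells it was 183, 121 without those genes too and 109 without the macrophage-marked sub-cluster too (3 higher). Doublet calls followed each cell filter, so those settings changed them too: the large removal fell on Control replicate 2 as reported (6.79%), on HAPC replicate 2 with 1000 or more UMIs (7.36%), on both with every barcode, and on neither under 20% mitochondrial UMIs or with 50 or more genes, settings with counts near that with doublets kept. edgeR's estimated prior degrees of freedom, which set how much genes share their spread, were 5.27 as reported, 3.38 with 1000 or more UMIs and 8.62 under 20% mitochondrial UMIs. Leaving out 1 library gave 120 to 1750.

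In intermediate cells the count was 11 with DESeq2, 105 without the expression filter, 16 without genes over 10 times higher in another class and 46 without lymphocyte-marked cells (11 to 126 with 1 library left out), and in late cells 7 with DESeq2 and 8 without such genes (4 to 47). DESeq2 called 65 genes in B cell-like, 111 in dendritic cell-like, 18 in macrophage-like, 75 in neutrophil-like, 4 in plasma cell-like, 38 in progenitor-like and 11 in T cell-like cells, where its size factors in edgeR called 3. Without the expression filter the same classes gave 404, 533, 127, 427, 135, 326 and 115, and NK cell-like cells 105. Without genes over 10 times higher in another class, dendritic cell-like cells had 1 call and macrophage-like, NK cell-like and progenitor-like cells 0. With 1 library left out the counts were 30 to 704 for B, 12 to 141 for dendritic, 3 to 509 for macrophage, 3 to 84 for NK, 15 to 739 for neutrophil, 15 to 486 for plasma, 3 to 388 for progenitor and 10 to 67 for T cell-like cells, and 715 to 2071 over all cells.

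With an estimated correlation 0 gene lists were called in any class, and fry called 2 in neutrophil-like cells, 1 in progenitor-like cells and 0 elsewhere. With 1 library left out the lists called were 2 to 3 in B, 5 to 7 in dendritic, 1 to 6 in NK, 6 to 12 in neutrophil, 5 to 9 in plasma, 2 to 6 in T, 2 to 6 in intermediate and 4 to 7 in late erythroid-like cells.

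The replicate block was fitted although the labels tie no animal or batch to a number. Over genes, the log2 CPM differences, replicate 1 minus replicate 2, of Control and of HAPC correlated at 0.286 in erythroid-like cells. This correlation was -0.262 in B cell-like cells and -0.220 over all cells. With the replicate block 0 classes were called (erythroid-like cells at 2.14, edgeR adjusted p = 0.101), early cells were no longer called (1.26), intermediate cells were (0.62), and 4 sub-clusters passed. Genes called with the replicate block numbered 2918 in erythroid-like, 72 in intermediate, 69 in late, 73 in B, 3 in dendritic, 170 in macrophage, 61 in NK, 0 in neutrophil, 0 in plasma, 163 in progenitor and 5 in T cell-like cells, where 6 lists were called. The crossed pairing called 5 classes, neutrophil-like cells among them (1.31, edgeR adjusted p = 0.00734) with no monocyte-like class, 840 genes in erythroid-like and 64 in intermediate cells.

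Named genes changed sign in 15 values, none called as reported. Hmox1 turned to 0.0675 with library size only, 0.47 with the mixed cluster and -0.95 to 0.21 with 1 library left out. The mixed cluster turned Kit to 0.13, Hba-a1 to 0.0529 and Alas2 to 0.0817. Without lymphocyte-marked cells Epor stood at -0.0149 (-0.0151 with DESeq2) and Tfrc at -0.0949 (-0.0958 with DESeq2), and leaving out genes over 10 times higher in another class as well gave the same 2 values as edgeR without those cells. With the macrophage-marked sub-cluster left out too, Epor stood at -0.0638, Tfrc at -0.131 and Hmox1 at 0.0477.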

Other observations

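The tests of single clusters, of stage make-up, of lymphocyte transcripts, of doublets of erythroid cells with B cells or macrophages, of free B cell RNA and of free erythroid RNA in the typical NK cell-like cell were chosen after the result was seen. B cell-like cells differed in make-up. Cluster 4, led by Cr2, Myc and Fcrl5, held 18.1% and 22.6% of B cell-like cells in the Control libraries and 8.64% and 8.91% in the HAPC libraries (log2 fold change -1.21, SE 0.30, edgeR adjusted p = 0.00919 over 6 clusters). Over all cells the same cluster held 8.85%, 12.1%, 3.33% and 2.78% and did not pass (log2 fold change -1.78, edgeR adjusted p = 0.0524). Cluster 1, led by Ighd and Fcer2a, held 34.2% and 26.8% of B cell-like cells in Control and 51.1% and 54.3% in HAPC libraries (0.79, edgeR adjusted p = 0.0545). Over all cells only erythroid clusters 22, led by histone genes, and 23, led by Car1, passed (2.84 and 2.96, edgeR adjusted p = 0.0275 each).

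Cell cycle genes were also higher as a group in macrophage-like cells of HAPC libraries, where G2 and M phase genes had a median of 1.23 with 0 of 23 passing over all genes and 1 adjusted over the list alone (camera adjusted p = 1.20e-09; adjusted p = 0.844 with an estimated correlation). In that class the erythroid gene Car1 was the only gene to pass (4.91), and without genes over 10 times higher in another class 0 passed by edgeR, with 454 at an unadjusted p under 0.05. Glycolysis genes were higher as a group in progenitor-like cells (median 0.57, 0 of 18 passing over all genes and 6 adjusted over the list alone; camera adjusted p = 0.000149, adjusted p = 0.568 with an estimated correlation). Barcodes under 200 genes with mostly globin UMIs made up 1.59% ± 0.426 of Control and 1.93% ± 0.0454 of HAPC barcodes (SD, n = 2 each; exact two-sided permutation p = 0.333, the smallest possible). They numbered 200 and 109 beside 354 and 391 erythroid-like cells kept in Control, and 186 and 181 beside 1283 and 2071 in HAPC libraries. The limit of 200 genes thus left out relatively more of them in Control. With 50 or more genes per cell the erythroid-like share was 3.54-fold higher in HAPC, against 4.38-fold as reported. Stage shares were not rerun with that limit.

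S phase and replication genes were higher in HAPC erythroid-like cells, with a median log2 fold change of 0.768 over the 26 genes of the S phase list. Mixing fixed profiles of the 10 sub-clusters by each library's shares gave a median of 0.661, a ratio of 0.861. This ratio cannot show stage make-up as the cause, since the profiles came from the same cells and cycle genes were not left out of clustering. The sub-clusters themselves differed in cycle genes, with sub-cluster 9 led by Ccne2 and Tcf19. They are also not stages alone, since 97.5% of sub-cluster 0 was lymphocyte-marked and the macrophage-marked sub-cluster was among them. Without lymphocyte-marked cells the median was 0.289, a ratio of 0.376 that lies between the bounds set for a full cause and for none, so lymphocyte transcripts in the same barcodes cannot be told apart from other sources. Within intermediate cells the list had a median of 0.38 with 0 of 23 passing over all genes and 2 adjusted over the list alone (camera adjusted p = 5.03e-05; adjusted p = 0.787 with an estimated correlation, and camera adjusted p = 0.239 without Control replicate 2), so a change within cells under hypoxia stays open.

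In HAPC erythroid-like cells MHC class II genes were called lower as a group by camera at the preset correlation. B cell markers, not tested as a group there, had a median log2 fold change of -2.25. Free RNA of B cells would lower the same markers in other cells, but their median was 0.611 in T cell-like and 0.459 in NK cell-like cells. These medians are of summed counts, which can rest on few cells. The 5% of T cell-like cells with the most Cd74 held 68.3% to 89.4% of it per library. The sums therefore cannot show whether free B cell RNA fell. The macrophage-marked sub-cluster held 1.71% and 3.51% of the class's MHC class II UMIs in the Control libraries, where their CPM was lower by 70.6% in HAPC, which argues against macrophages there as the cause over the whole class. Among cells without lymphocyte markers it held 24.7% and 42.1% of those UMIs in Control, and leaving it out moved the list's median from -2.25 to -1.77 and left 400 and 106 CPM in Control and 69.7 and 111 CPM in HAPC libraries, which overlap, so there it cannot be told apart from other causes. Lymphocyte-marked cells held 83.8% to 94.3% of the class's MHC class II UMIs. Their share of the class was 23.2% and 21.0% in the Control and 14.9% and 7.24% in the HAPC libraries. It changed 0.501-fold against 0.681-fold for B cell-like cells, a ratio of 1.36. A like change was predicted for B and erythroid cells in 1 barcode. The share also counts cells marked by T cell genes alone, so this ratio cannot weigh for them. The 3 B cell markers tested in late cells had a median of -2.06, where such barcodes were taken to give a smaller fall. That median cannot weigh against them, since it rests on 3 markers and Cd74 was detected less often in late than in T cell-like cells of each library. Lymphocyte-marked cells had medians of 17178 to 23585 UMIs and 2290 to 2829 genes per library. Those of unmarked erythroid-like cells were 12771 to 15160 UMIs and 412 to 1496 genes. Lymphocyte and erythroid cells in 1 barcode would give such a difference, but cells with more UMIs also reach 3 marker genes more easily. B and erythroid cells in 1 barcode thus cannot be told apart from a change within erythroid cells.

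Globin transcripts were higher in NK cell-like cells of HAPC libraries. Free erythroid RNA would reach all classes alike, and median globin UMIs per cell were 3 in NK, B and T cell-like cells of the Control libraries and 7.5 and 11 in NK, 7 and 8 in B and 7 and 9 in T cell-like cells of the HAPC libraries (largest ratio 1.375), so it may account for the typical cell. By mean, NK cell-like cells of the HAPC libraries held 4.43 to 13.9 times the globin UMIs per cell of B and T cell-like cells, which argues against free RNA as the source of the summed rise. The 5% of NK cell-like cells with the most globin UMIs held 87.5% and 96.5% of them in the HAPC libraries, so erythroid cells in the same barcodes as NK cells may be the source of those.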
